A study of Rattus norvegicus with 16 samples.

How the data were processed

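Expression was measured by RNA sequencing in adrenal gland, heart and pancreas of male Sprague-Dawley rats that received vehicle or benzalkonium chloride (BKC), a quaternary ammonium disinfectant, into the trachea. Per the labels, 50 or 100 µg of BKC was given per rat and instillation, 10 times at intervals of 3 days from 7 weeks of age. Organs were taken on day 31, 24 h after the last dose. The 2 adrenal glands of an animal were pooled, the heart piece was described as left ventricular, and libraries were made with a stranded mRNA kit. There were 16 samples in 8 groups of 2 libraries: adrenal gland and heart with vehicle, BKC50 and BKC100, and pancreas with vehicle and BKC100. All 16 sample columns were matched to their samples by library name, and 0 were left unmatched.

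The deposited tables gave 1 value per gene and library for 45777 gene symbols, and these values were read as FPKM (fragment counts scaled by transcript length and library size). The tables did not state the unit. It was inferred from the values, which were not whole numbers and whose sums differed between libraries, as TPM sums do not. The authors' processing notes named HISAT2 2.1.0, StringTie 2.1.3b and edgeR 3.40.2 without their roles. The genome build was not given in the sources used here. All 45777 symbols were found in the gene list of assembly GRCr8, which was used only for symbols and gene classes. Read counts and the depth of each library were unknown, so no counting intervals or detection floors were computed. The sum of FPKM per library ranged from 391123 to 1004890 in adrenal gland, from 356725 to 476434 in the 5 heart libraries used and from 486061 to 603063 in pancreas.

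The heart BKC100 replicate 2 column was equal to the adrenal BKC100 replicate 2 column in 45777 of 45777 genes. It was kept as an adrenal library and left out of the heart, which departs from the plan of 6 heart libraries. Heart BKC100 was therefore a lone library with no replicate check, assumed to vary like the other heart libraries. The 15 libraries left were analysed as independent animals, although libraries of different organs with the same animal label may come from 1 rat.

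Each organ was fitted apart with limma 3.58.1 in R 4.3.3, with sample descriptions read by jsonlite 2.0.0. The model used log2(FPKM + 1), 1 mean per group, a mean-variance trend and robust variance shrinkage over all groups of the organ. Genes with a mean of at least 1 FPKM over the organ's libraries were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "rose" and "fell" are used for called genes only. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes near 0. Errors of fold changes are standard errors, and errors of FPKM means are standard deviations. The 7 comparisons set each dose against vehicle and BKC100 against BKC50. Groups of 2 allowed no count of other splits of the samples and no test for outlying libraries.

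A set of 41 gene lists, fixed before the data were examined together with the tests, the alternatives and the rule for naming genes, was tested with camera in limma. The correlation between genes was preset at 0.01, and lists with at least 5 members tested were adjusted within a comparison. Beside each, camera with an estimated correlation was run, and members were also adjusted over the list alone. For the lone heart library, list medians were set against 10000 random lists matched on mean expression. The genes called at both doses were compared with the product expected from independent calls. In adrenal gland they were also compared with 100 simulations of unchanged groups that share the 2 vehicle libraries. These simulations were fitted without robust shrinkage.

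Named genes were chosen by a rule. Among called genes with groups that did not overlap and a mean log2 level of at least 1, it took the 10 largest rises and falls with a gene symbol other than a placeholder. For the comparison of doses it took 3 each way. It added up to 4 members, by smallest p, of each list that was called or had at least 3 called members. With fewer than 5 called genes it took the 8 with the smallest p. It always included Star, Cyp11a1, Cyp11b1, Cyp11b2, Th and Pnmt in adrenal gland, Nppa, Nppb, Myh6 and Myh7 in heart, and Ins2, Gcg, Prss1 and Cpa1 in pancreas. Other genes named below were chosen after their values were seen.

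Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, the replicate number as a block, only the 2 groups compared, a fold change of at least 2, the naming style of the heart libraries as a covariate, and each library left out in turn. Alternatives added after the data were seen were median-ratio scaling, quantile normalization, protein-coding genes rescaled to equal sums, limma without robust shrinkage, all 6 heart columns as deposited, and the adrenal gland against pancreas difference as a limma interaction over 8 libraries. Tests and scalings that need read counts were not run, nor was the planned test across the 3 organs, which needed counts. The pipeline was tested on simulated data with 200 changed genes per comparison, all with a mean log2 level of at least 2. At a log2 change of 2 it called 98.5% of them in adrenal gland at either dose, 95.5% in heart at BKC50, 89.4% with the lone BKC100 heart and 98.5% in pancreas. At a log2 change of 1 the shares were 43.3% and 59.7% in adrenal gland at BKC50 and BKC100, 28.4% and 7.46% in heart, and 16.4% in pancreas. Unchanged genes called were 21 and 28 in adrenal gland, 11 and 14 in heart and 6 in pancreas, so the share of false calls passed 5% in adrenal gland and heart.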

Results

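Values are FPKM means ± SD of 2 libraries per group, except for the lone BKC100 heart library. The named genes that rose or fell had both libraries of a group on the same side of both libraries of the other. Adjusted p values of genes are from limma, and those of gene lists are from camera. No list call in any of the 7 comparisons held with an estimated correlation between genes: 0 lists passed, against 8 to 10 per adrenal comparison with the preset correlation. On simulated data camera was run with the preset correlation only. It is therefore unknown whether camera with an estimated correlation could call a shifted list in groups this small.

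The metallothionein genes, which encode small metal-binding proteins induced by zinc and glucocorticoids, fell in the adrenal gland at 100 µg BKC. Mt2A fell from 224 ± 90.4 FPKM in vehicle to 17.9 ± 1.34 (log2 change -3.51, SE 0.29, adjusted p = 0.000474, n = 2 per group). Mt1 fell from 162 ± 16.5 to 30.6 ± 11.4 (log2 change -2.41, SE 0.25, adjusted p = 0.000682). In the other direction, the phosphodiesterase gene Pde10a rose from 2.35 ± 2.04 to 48.5 ± 9.92 (log2 change 4.02, SE 0.41, adjusted p = 0.00369). Elovl6, which encodes a fatty acid elongase, rose from 1.78 ± 0.886 to 20.8 ± 8.56 (log2 change 2.95, SE 0.42, adjusted p = 0.00817). The mevalonate pathway enzyme genes Idi1 and Hmgcs1 rose by 1.81 (SE 0.25) and 1.67 (SE 0.26) on the log2 scale. Idi1 went from 28.1 ± 0.457 to 102 ± 20.3 FPKM and Hmgcs1 from 41.3 ± 0.625 to 135 ± 27.4.

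Further falls included the cytokine receptor gene Il23r, from 56.7 ± 3.04 to 10.2 ± 1.98 FPKM (log2 change -2.38, SE 0.22, adjusted p = 0.000357). Apbb1 and the nuclear receptor gene Nr0b2 fell, with log2 changes of -2.33 and -2.24. Agfg2, C2h3orf33, Ndnf, Fam83b and Tmem86a fell as well, with log2 changes between -2.18 and -2.06. Lrat, which encodes a retinol-esterifying enzyme, rose from 23.6 ± 0.927 to 121 ± 74.2 (log2 change 2.16, SE 0.40). Apart from the heat shock gene Hspa1b, given below, the other rises among the 10 largest taken by the rule were in small RNA genes and a pseudogene. Snord97 rose from 11.6 ± 6.42 to 393 ± 93.5 (log2 change 5.04, SE 0.36), Scarna18 by 3.86, Snord15b by 2.40, Snora71a by 2.20, Mir341 by 2.19 and Pou5f1-ps3 by 2.32. Many of these lie inside introns of host genes, and reads of a pseudogene may belong to its parent gene.

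Of 24 genes of cholesterol biosynthesis and uptake tested, 9 rose, 1 fell (Pmvk, log2 change -0.83) and 14 did not pass. Beside Idi1 and Hmgcs1, Hsd17b7 rose by 1.53, Insig1 by 1.47, Cyp51 by 1.31 and Srebf2 by 1.04 on the log2 scale. Cyp51 went from 35.6 ± 7.98 to 88.8 ± 0.122 FPKM. The list was called (adjusted p = 3.5e-12, and adjusted p = 0.948 with an estimated correlation), and adjusted over the list alone 10 rose and 1 fell. Without vehicle replicate 1, Hsd17b7 (adjusted p = 0.075) and Cyp51 (adjusted p = 0.0516) no longer passed.

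Of 22 heat shock genes, Hspa1b and Hspa1a rose by 2.47 and 2.15 on the log2 scale, Cryab fell by 1.42, and 19 did not pass. Hspa1b went from 2.86 ± 0.811 to 22.7 ± 15.0 FPKM, and reads of these 2 near-identical genes cannot be told apart with certainty. The list was called upward (adjusted p = 0.00068, and adjusted p = 0.948 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell. Of the 3 heat shock gene calls, 1 remained under median-ratio scaling or quantile normalization, and 3 with protein-coding genes at equal sums. Among 15 clock genes Per2 rose by 1.80, Npas2 and Bmal1 fell (log2 changes -1.47 and -1.11), and 12 did not pass. Per2 went from 1.42 and 1.70 FPKM to 5.51 and 11.2. The clock list was called (adjusted p = 0.0314, and adjusted p = 0.948 with an estimated correlation), with 2 up and 2 down adjusted over the list alone. That call ended under median-ratio scaling (adjusted p = 0.113) and without BKC100 replicate 2 (adjusted p = 0.151). Npas2 did not pass without vehicle replicate 1 (adjusted p = 0.0516) or BKC100 replicate 1 (adjusted p = 0.0604). Bmal1 did not pass without vehicle replicate 2 (adjusted p = 0.0915) or BKC100 replicate 1 (adjusted p = 0.0642). Hspa1b did not pass without vehicle replicate 1 (adjusted p = 0.0955), nor Cryab without vehicle replicate 2 (adjusted p = 0.0513).

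Lipid use genes split. Among 26 genes of fatty acid oxidation and PPAR targets, Cpt1a rose from 43.4 ± 2.11 to 105 ± 40.4 FPKM (log2 change 1.21), the lipid droplet genes Plin5 and Plin2 fell (log2 changes -1.13 and -0.69), and 23 did not pass. The list was called upward (adjusted p = 0.00218, and adjusted p = 0.948 with an estimated correlation; 3 up and 3 down adjusted over the list alone), but not without BKC100 replicate 2 (adjusted p = 0.196). Among 18 genes of fatty acid synthesis, Elovl6 and Mlxipl rose, Scd2 and Srebf1 fell and 14 did not pass, and the list was not called (adjusted p = 0.0683). Mlxipl went from 5.50 ± 1.25 to 19.8 ± 0.374 FPKM. Of the 3 fatty acid oxidation gene calls 1 remained under median-ratio scaling, and of the 4 fatty acid synthesis calls 2. Quantile normalization and protein-coding genes at equal sums kept the same numbers. None of 17 adipocyte markers passed, although camera called the list upward (adjusted p = 0.00573, and adjusted p = 0.948 with an estimated correlation). That call ended under median-ratio scaling (adjusted p = 0.113), without vehicle replicate 1 (adjusted p = 0.0623) and without BKC100 replicate 2 (adjusted p = 0.978).

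The interferon and cell cycle lists were called downward at BKC100 with few members passing. Of 33 interferon response genes, Cxcl10 fell from 16.9 ± 3.87 to 4.03 ± 0.337 FPKM (log2 change -1.82, SE 0.29), Irf1, Ifi27 and Psmb8 also fell, and 29 did not pass. That list was called (adjusted p = 0.00218, and adjusted p = 0.948 with an estimated correlation), and adjusted over the list alone 6 fell. Of 25 cell cycle genes, Cenpf, Mcm2, Rrm1 and Tyms fell and 21 did not pass, and adjusted over the list alone 11 fell. The cell cycle list was called (adjusted p = 0.00185, and adjusted p = 0.948 with an estimated correlation), but not without vehicle replicate 1 (adjusted p = 0.15). Of 36 nuclear genes of oxidative phosphorylation, 6 fell, among them Cox7b (log2 change -0.79) and Ndufs3 (log2 change -0.76), and 30 did not pass. Adjusted over the list alone 10 fell. That list (adjusted p = 0.0314, and adjusted p = 0.948 with an estimated correlation) was not called under median-ratio scaling (adjusted p = 0.246), without vehicle replicate 2 (adjusted p = 0.14) or without BKC100 replicate 2 (adjusted p = 0.612). Of 10 MHC class II genes, RT1-Ba and RT1-Bb fell (log2 changes -1.30 and -1.05) and 8 did not pass. The MHC class II (adjusted p = 0.277), inflammatory and macrophage lists (adjusted p = 0.311 each) were not called. Under median-ratio scaling or quantile normalization, 1 of the 4 interferon gene calls remained, and 0 of the 4 cell cycle and 0 of the 6 oxidative phosphorylation gene calls. Protein-coding genes at equal sums kept 2, 0 and 0 of them. The interferon and cell cycle lists were still called by camera under median-ratio scaling with the preset correlation (adjusted p = 0.000187 and 0.000104).

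Steroid hormone genes did not move one way. Of 25 steroidogenesis genes, the ferredoxin gene Fdx1 and the lipoprotein receptor gene Scarb1 rose by 0.97 and 1.84, Tspo, Fdxr and Cyb5a fell (log2 changes -1.18, -0.99 and -0.94), and 20 did not pass. Tspo went from 602 ± 37.9 to 265 ± 9.01 FPKM. The list was not called (adjusted p = 0.339), adjusted over the list alone 3 rose and 3 fell, and of the 5 calls 0 remained under median-ratio scaling and 2 with protein-coding genes at equal sums. Star, which encodes the protein that carries cholesterol into mitochondria, averaged 7632 ± 1667 against 3514 ± 1642 FPKM and did not pass (log2 change 1.18, adjusted p = 0.0573). It passed without vehicle replicate 2 (adjusted p = 0.00019) and without BKC100 replicate 2 (adjusted p = 0.0237). Cyp11a1, Cyp11b1, Cyp11b2, Th and Pnmt did not pass, with log2 changes of -0.23, -0.56, -0.63, -0.27 and 0.69.

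Of 22 glucocorticoid response genes, 5 fell and 17 did not pass. They were Mt1, Mt2A, Tsc22d3 (log2 change -1.14), Sult1a1 and Klf15, and adjusted over the list alone 5 fell. Of 28 NRF2 target genes, Hmox1 fell from 19.6 ± 9.32 to 4.54 ± 1.69 FPKM, Gsta1, Gstp1 and Txn1 also fell and 24 did not pass. Of 17 hypoxia response genes, Pfkfb3 rose, Bnip3 and Ldha fell and 14 did not pass. None of these 3 lists was called by camera (adjusted p = 0.669, 0.903 and 0.903). Under median-ratio scaling or quantile normalization, 0 of the 4 NRF2 and 0 of the 3 hypoxia gene calls remained, and 3 of the 5 glucocorticoid response calls. Protein-coding genes at equal sums kept 3, 2 and 3 of them.

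**Figure D1:**
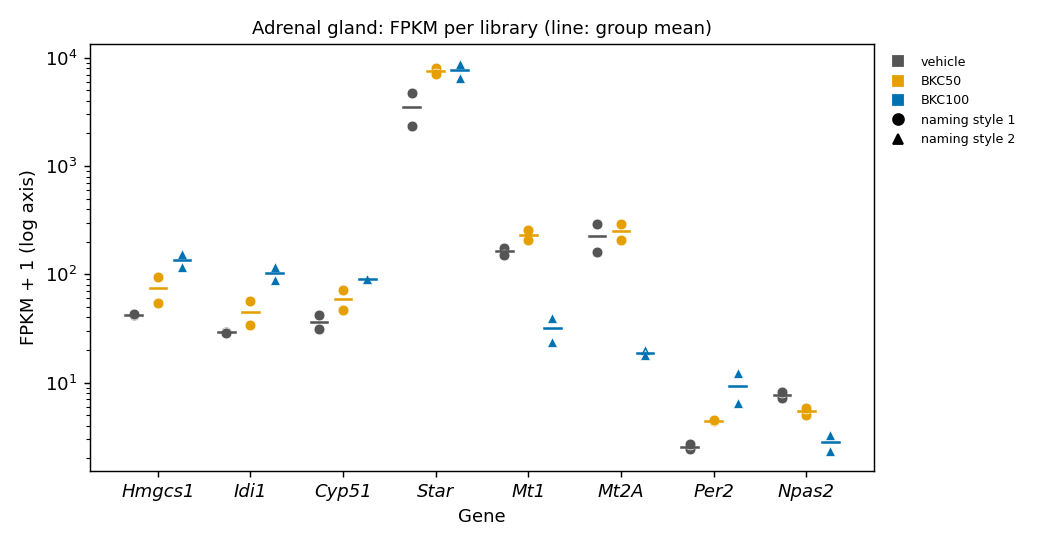
Adrenal FPKM + 1 on a log axis for each library by treatment group, with circles and triangles for the 2 library naming styles and a line at each group mean. Mt2A lay at 17.9 ± 1.34 in BKC100 against 224 ± 90.4 in vehicle, and Hmgcs1 at 135 ± 27.4 against 41.3 ± 0.625.

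In total, limma called 1230 of 12578 adrenal genes at BKC100 against vehicle, 226 up and 1004 down, with 3776 at an unadjusted p under 0.05. The median log2 change of all genes was -0.28, so smaller falls were near the general shift. With median-ratio scaling 330 genes were called, 215 up and 115 down, of which 281 were also called before. Quantile normalization gave 232 up and 165 down, and protein-coding genes at equal sums gave 300 up and 251 down. Against 60 named genes that passed, 25 did so after median-ratio scaling. Without vehicle replicate 1, 261 genes were called and 31 of the 60 remained, and without BKC100 replicate 1, 327 and 32. Without BKC100 replicate 2, 2304 were called and 53 remained. With no filter on low values, 0 genes passed (4551 at an unadjusted p under 0.05). Mt1, Mt2A, Il23r, Apbb1, Nr0b2, Tmem86a, Cxcl10, Tsc22d3, Cpt1a, Hmgcs1, Idi1, Mlxipl, Per2, Pde10a and Elovl6 passed under every alternative run except the unfiltered one. Library names fell into 2 styles, and all BKC100 adrenals had the second while the others had the first. No fit with style as a term could be had for BKC100, so by the design the naming style and the 100 µg dose cannot be told apart in this organ, while vehicle and BKC50 had the same style. The small RNA Rn7sl1 took 27.0% to 35.9% of FPKM in the first style and 10.3% and 9.50% in the BKC100 adrenals.

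At 50 µg the chemokine gene Cxcl10 fell in the adrenal gland, from 16.9 ± 3.87 to 3.49 ± 1.17 FPKM (log2 change -2.01, SE 0.29, adjusted p = 0.0462, n = 2 per group). Pde10a averaged 22.8 ± 1.32 against 2.35 ± 2.04 FPKM (log2 change 2.97) and did not pass (adjusted p = 0.0784). Cnr1, which encodes a cannabinoid receptor, did not pass at a log2 change of -1.45 (adjusted p = 0.0609). The haemoglobin genes Hba-a1 and Hba-a2 had log2 changes of 1.18 and 1.06 (adjusted p = 0.0609 and 0.079), and Hba-a1 averaged 269 ± 42.8 against 117 ± 4.22 FPKM. The sterol reductase gene Dhcr7 had a log2 change of 1.12 (adjusted p = 0.0823), Rnu1-136 of 1.75 and Rpl36l2 of 1.56, none of them passing. Star averaged 7595 ± 747 against 3514 ± 1642 FPKM (log2 change 1.19, adjusted p = 0.252). Cyp11a1, Cyp11b1, Cyp11b2, Th and Pnmt had log2 changes of -0.20, -0.66, 0.04, 0.40 and 1.34 and did not pass.

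Of 24 cholesterol genes, 0 passed over all genes and Dhcr7 alone rose adjusted over the list alone, while 22 had a positive change. That list was called upward at 50 µg (adjusted p = 8.77e-08, and adjusted p = 0.818 with an estimated correlation). All 7 erythroid genes had a positive change, 4 rose adjusted over the list alone, and the list was called (adjusted p = 7.4e-07, and adjusted p = 0.818 with an estimated correlation). Both calls held whichever library was left out. Another 4 lists were called upward with 0 members passing over all genes: collagen (adjusted p = 0.0132), steroidogenesis and medulla markers (adjusted p = 0.0315 each) and heat shock (adjusted p = 0.0369), with 0.818 each with an estimated correlation. Another 4 were called downward: interferon response, in which Cxcl10 fell and 30 of 33 were negative, cell cycle and inflammatory genes (adjusted p = 0.0315 each), and p53 targets (adjusted p = 0.0434). Their adjusted p with an estimated correlation was 0.886, 0.861, 0.818 and 0.818. Adjusted over the list alone, 1 steroidogenesis, 2 medulla, 2 heat shock and 0 collagen genes rose, and 2 interferon, 1 cell cycle, 1 inflammatory and 1 p53 genes fell.

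Each of these last 8 calls ended when 1 library was left out. Without vehicle replicate 1, steroidogenesis (adjusted p = 0.415), collagen (0.131), heat shock (0.0895), interferon (0.101) and cell cycle (0.627, with the test's direction reversed) were not called. Without BKC50 replicate 1 the interferon median was 0.22 (adjusted p = 0.143), and steroidogenesis (0.566), collagen (0.208) and cell cycle (0.212) were not called. Without vehicle replicate 2, medulla markers (adjusted p = 0.271), inflammatory genes (0.756) and p53 targets (0.736) were not called. Without BKC50 replicate 2, medulla markers (0.18), heat shock (0.114), inflammatory genes (0.0755) and p53 targets (0.309) were not called.

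Limma called 4 of 12578 genes at BKC50 against vehicle, 1 up and 3 down, with 1424 at an unadjusted p under 0.05 and an all-gene median of -0.10. Beside Cxcl10 these were Ubbl3, LOC120093942 and LOC120096853, which were named after their values were seen. Cxcl10 did not pass without vehicle replicate 1 (adjusted p = 0.133) or BKC50 replicate 1 (adjusted p = 0.128). It did not pass either with a pseudocount of 0.1 (0.0893), limma without robust shrinkage (0.125), median-ratio scaling (0.145), the replicate block (0.164), quantile normalization (0.186) or no filter (0.533), and its adjusted p ranged from 0.00214 to 0.533 over the alternatives. The count was 1 without BKC50 replicate 1, 10 without vehicle replicate 1, 113 without vehicle replicate 2 and 32 without BKC50 replicate 2. Without BKC100 replicate 1 or 2 it was 183 or 160. BKC50 replicate 1 stood apart from the other 3 libraries of its style, with 26.0% of FPKM in the small RNA Rpph1 against 8.69% to 12.5%, and a sum of 1004890 FPKM against 689355 to 710106.

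Between the doses, BKC100 adrenals had less metallothionein RNA than BKC50 adrenals. The BKC50 adrenals had the first naming style and the BKC100 adrenals the second, so dose and style cannot be told apart in this comparison. Mt2A fell from 249 ± 62.4 at 50 µg to 17.9 ± 1.34 FPKM at 100 µg (log2 change -3.70, SE 0.29, adjusted p = 0.000433), and Mt1 had a log2 change of -2.92 (adjusted p = 0.000354). The small nucleolar RNA gene Snora74a fell from 393 ± 57.3 to 69.9 ± 3.43 FPKM (log2 change -2.47). Snord97, Scarna18 and Scarna17 rose by 4.32, 3.43 and 2.17. Of 7 erythroid genes, 5 fell, among them Hba-a2 (log2 change -1.65) and Hba-a1 (log2 change -1.43), and 2 did not pass. That list was called (adjusted p = 4.73e-06, and adjusted p = 0.891 with an estimated correlation), adjusted over the list alone 6 fell, and of the 5 calls 1 remained under median-ratio scaling and 4 with protein-coding genes at equal sums. Of 26 fatty acid oxidation genes, Acadl and Decr1 rose by 0.97 and 0.90, also adjusted over the list alone, and 24 did not pass (adjusted p = 2.87e-05, and adjusted p = 0.891 with an estimated correlation). Of 24 cholesterol genes Idi1 rose by 1.21, and the list (adjusted p = 0.000986, and adjusted p = 0.891 with an estimated correlation) was not called without BKC50 replicate 2 (adjusted p = 0.419). Limma called 372 genes, 78 up and 294 down, with 2384 at an unadjusted p under 0.05 and an all-gene median of -0.16. With median-ratio scaling 38 were called, 18 up and 20 down, and all 6 genes named for this comparison by the rule remained. Without BKC50 replicate 2, 81 genes were called, without BKC100 replicate 1, 173, and without BKC100 replicate 2, 870.

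Between the doses, 7 further lists were called with adjusted p = 0.891 each with an estimated correlation. Adipocyte markers (adjusted p = 0.0209, 0 of 17 passing) and heat shock genes (adjusted p = 0.0289) were called upward, although Cryab and Hspb1 fell and 20 of 22 heat shock genes did not pass. MHC class II genes, in which RT1-Bb fell, macrophage markers, in which Tyrobp fell, and smooth muscle markers, in which Tagln fell, were called downward (adjusted p = 0.0389 each). Oxidative phosphorylation (adjusted p = 0.0242) and cell cycle genes (adjusted p = 0.0483) were called downward with 0 members passing. Adjusted over the list alone, 2 heat shock genes rose and 2 fell, and 1 MHC class II, 2 macrophage and 2 smooth muscle genes fell. Without BKC100 replicate 2, adipocyte markers (adjusted p = 0.893), oxidative phosphorylation (0.358), MHC class II (0.245), macrophage (0.0901), smooth muscle (0.164) and cell cycle genes (0.171) were not called. Without BKC50 replicate 2, heat shock (0.0593), MHC class II (0.476), macrophage (0.297) and cell cycle genes (0.419) were not called. Heat shock (0.143) and macrophage genes (0.0696) were not called without BKC100 replicate 1, nor adipocyte (0.329) and smooth muscle markers (0.188) without BKC50 replicate 1. With median-ratio scaling, adipocyte markers and oxidative phosphorylation (0.0918 each) were not called, and with the replicate block, smooth muscle (0.0521) and cell cycle genes (0.0751) were not called.

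The doses shared their 2 vehicle libraries, which could not be split, so part of any overlap may come from them. At the adjusted threshold 2 adrenal genes fell at both doses, against 0.239 expected from independent calls and 0.53 genes in simulations with shared controls. At an unadjusted p under 0.01 the overlap was 206 genes, 64 up and 142 down, against 3.26 and 35.8 expected and 25.4 simulated. The simulations were fitted without robust shrinkage, unlike the observed calls. Fitted that way, limma called 0 adrenal genes at BKC50 at the adjusted threshold. The observed and simulated counts thus differ in setting, and no conclusion is drawn from them. Across genes, which are not independent replicates, the log2 changes at both doses correlated at 0.569, against 0.501 simulated. Their covariance was 0.142 against 0.0534 simulated. In heart, 0 genes were shared at the adjusted threshold and 2 at an unadjusted p under 0.01, against 0.119 up and 0.140 down expected from independent calls, and the correlation was 0.0541. The simulations held no naming style, which vehicle and BKC50 hearts share, and were not used for heart.

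In the heart at 50 µg no gene passed. Slc35a4 averaged 6.32 ± 0.0289 against 1.79 ± 0.212 FPKM in vehicle (log2 change 1.39, adjusted p = 1, n = 2 per group). Kpna3, Dusp5 and Hamp had log2 changes of -1.02, -0.82 and -0.76, and C4bpb, Tomm70-ps1 and Reg3b of 0.80, 0.93 and 1.15, none passing. The natriuretic peptide gene Nppa averaged 72.5 ± 41.8 against 142 ± 100 FPKM (log2 change -0.88, adjusted p = 1). Nppb, Myh6 and Myh7 had log2 changes of -0.02, 0.08 and -0.32 and did not pass.

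Of 20 immediate early genes in the heart at 50 µg, 18 had a negative change, such as Btg2 (log2 change -1.10) and Nr4a1 (log2 change -1.28). Their list was called downward (adjusted p = 5.79e-11, and adjusted p = 0.719 with an estimated correlation). All 11 atrial and conduction markers had a negative change (adjusted p = 6.36e-05, and adjusted p = 0.719 with an estimated correlation). Some of these changes were close to none: Bmp10 was at 0.00598 and 0 FPKM in vehicle against 0 and 0 in BKC50. Tbx3 was at 0.806 and 1.62 FPKM against 0.858 and 1.52. Bmp10 and Sln averaged 0.0015 and 0.925 FPKM outside the BKC100 heart, and passed the filter on low values only through it. Neither list was called without vehicle replicate 1 (adjusted p = 0.322 and 0.26), in which Btg2 was at 60.9 FPKM against 28.3 in replicate 2. Of 36 interferon genes 32 had a positive change and the list was called upward (adjusted p = 6.36e-05, and adjusted p = 0.969 with an estimated correlation). Without vehicle replicate 2 it was not called (adjusted p = 0.0747), and without BKC50 replicate 2 it was called downward (median -0.08, adjusted p = 0.00201). Macrophage markers were called upward (adjusted p = 5.66e-05, and adjusted p = 0.719 with an estimated correlation), but not without vehicle replicate 2 (adjusted p = 0.131) or BKC50 replicate 2 (adjusted p = 0.893). Smooth muscle markers were called upward (adjusted p = 0.00136, and adjusted p = 0.719 with an estimated correlation) and were not called with naming style as a covariate (adjusted p = 0.078). They were not called without vehicle replicate 2 (0.27), BKC50 replicate 1 (0.0924) or BKC50 replicate 2 (0.0546) either.

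Inflammatory genes were called downward in the same hearts (adjusted p = 0.0015, and adjusted p = 0.719 with an estimated correlation). They were not called without vehicle replicate 1 (adjusted p = 0.257), vehicle replicate 2 (adjusted p = 0.0517) or BKC50 replicate 1 (adjusted p = 0.596). Collagen genes were called downward (adjusted p = 0.015, and adjusted p = 0.969 with an estimated correlation). They were not called without BKC50 replicate 2 (adjusted p = 0.893) or vehicle replicate 1 (adjusted p = 0.652), where their median was 0.11. No member of these 7 lists passed, and adjusted over the list alone 0 passed. Limma called 0 of 12099 genes (45 at an unadjusted p under 0.05). Without vehicle replicate 1 or 2 it called 2. Vehicle and BKC50 hearts each held 1 library of each naming style, while the lone BKC100 heart had the second. With style as a covariate 0 genes passed and 588 had an unadjusted p under 0.05.

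The BKC100 heart library differed from the other hearts in genes that separate the chambers. It had 7906 FPKM of Myl7, the atrial regulatory myosin light chain gene, against 3.95 and 3.45 in vehicle. Myl4 was at 4148 against 3.69 ± 2.68 FPKM and Sln at 1884 against 2.79 and 0.222. Bmp10 was at 1704 FPKM and at or near 0 in the other 4 hearts. Nppa was at 17727 against 142 ± 100 FPKM and did not pass (adjusted p = 0.0578). The ventricular light chain genes were low: Myl2 was at 41.9 FPKM against 11675 to 18061 in the other 4 hearts and Myl3 at 12.3 against 2232 to 4327. Myh7, the slow myosin heavy chain gene, was at 347 against 1412 ± 162 FPKM (adjusted p = 0.0753), Myh6 at 3109 against 3920 ± 973 and Nppb at 598 against 330 ± 19.0, none of them passing.

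Other rises in this library were Mybphl (log2 change 7.08), the iron hormone gene Hamp (6.54), Acta2 (5.50), Myl1 (5.40), Sbk2 (5.14) and Cnn1 (4.89). The largest falls besides Myl2 and Myl3 were Penk (-6.09), Strit1 (-5.99), Lmod3 (-4.04), Ccl21 (-3.99), C6h14orf180 (-3.93), Fads6 (-3.72), Scn4b (-3.67) and Ncf1 (-3.58). Vsig4 rose to 13.2, Cxcl10 to 11.5, Vcam1 to 16.7 and Ptgs2 to 4.69 FPKM, against 0.0418 ± 0.0591, 0.561 ± 0.0497, 3.55 ± 0.203 and 0.261 ± 0.0554 in vehicle. Acadm, an enzyme gene of fatty acid oxidation, fell from 557 ± 26.7 to 84.8 FPKM.

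The 11 atrial and conduction markers had a median log2 difference of 3.33 from vehicle, at percentile 100 of 10000 random lists matched on mean expression, and 4 rose, 8 adjusted over the list alone. Interferon genes had a median of 0.88 (percentile 100), vasoactive system genes of 0.86 (percentile 100), inflammatory genes of 0.68 and macrophage markers of 0.51 (percentile 99.99 each), and cell cycle genes of 0.43 (percentile 99.39). Genes of fatty acid oxidation had a median of -1.07 (percentile 0), with Acadm falling and 26 not passing. Genes of oxidative phosphorylation lay at percentile 0.01 with 35 of 36 lower than in vehicle. Erythroid genes had a median of -2.34 (percentile 0), immediate early genes of -0.67 (percentile 0) and glycolysis genes of -0.64 (percentile 4.72). The sarcomere list had a median of -0.51 (percentile 34.43) and a mean of -1.37, with Myl2 and Myl3 falling. Calcium handling genes had a median of -0.38 (percentile 4.99), with Sln rising. The lists above were those called by camera, with adjusted p = 0.596 to 0.707 with an estimated correlation. Calcium handling genes were not called without vehicle replicate 1 (adjusted p = 0.252) or BKC50 replicate 2 (adjusted p = 0.0539) or with naming style as a covariate (adjusted p = 0.220), nor immediate early genes without vehicle replicate 1 (adjusted p = 0.185). Among lists not called, cardiac stress genes lay at percentile 100 (median 0.67), collagen at 99.86 and ER stress genes at 99.79, and cholesterol, fatty acid synthesis and NRF2 genes at 0.54, 0.84 and 0.92.

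**Figure D2:**
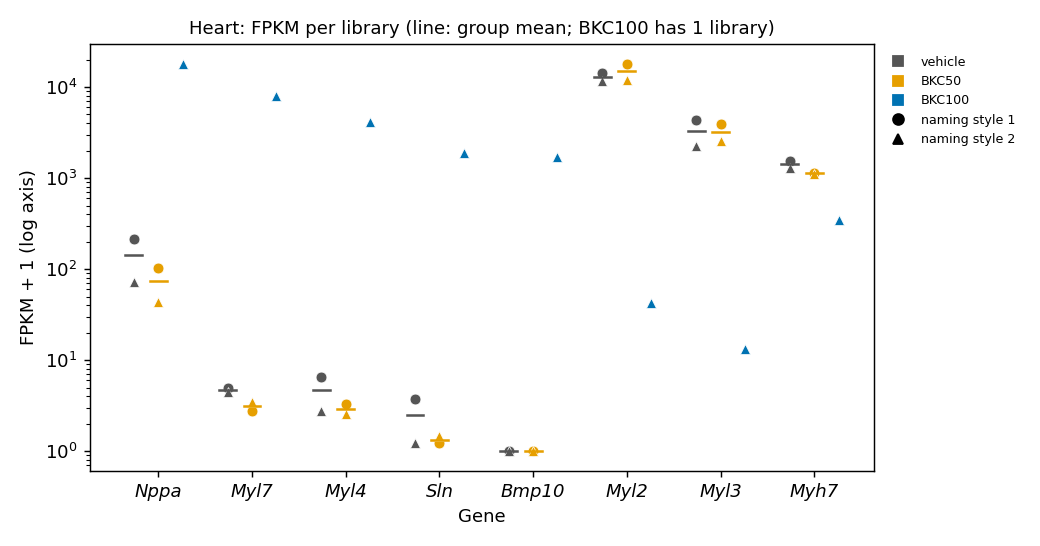
Heart FPKM + 1 on a log axis for each of the 5 heart libraries by treatment group, with circles and triangles for the 2 naming styles and a line at each group mean. The lone BKC100 library had 7906 FPKM of Myl7 and 41.9 of Myl2, against 11675 to 18061 of Myl2 in the other hearts.

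Limma called 98 of 12099 genes between the lone BKC100 heart and vehicle, 62 up and 36 down, with 2093 at an unadjusted p under 0.05. With median-ratio scaling the count was 255 (120 up and 135 down), and with naming style as a covariate 3545 (1733 up and 1812 down). The balance turned with a pseudocount of 0.1 (24 up and 57 down), and without a filter it was 528 up and 37 down. Leaving out BKC50 replicate 1 or 2 or vehicle replicate 1 or 2 gave 266, 289, 276 or 347 calls, and each kept all 25 named genes that passed. Against BKC50 the count was 106, 67 up and 39 down, with 2162 at an unadjusted p under 0.05, and Myl7, Bmp10 and Myl4 rose by 11.32, 10.74 and 10.48 and Myl2, Myl3 and Strit1 fell (log2 changes -8.41, -7.90 and -6.48). That count was 244 with median-ratio scaling (116 up and 128 down), and 536, 579 or 171 without vehicle replicate 1, vehicle replicate 2 or BKC50 replicate 2. As 1 library has no replicate, none of these differences can be told from differences between animals or pieces.

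In the pancreas at 100 µg the metallothionein gene Mt1 rose from 3.72 ± 0.974 to 18.0 ± 3.04 FPKM (log2 change 2.02, SE 0.36, adjusted p = 2.55e-05, n = 2 per group). Mt2A rose from 1.47 ± 0.837 to 5.86 ± 0.618 (log2 change 1.52, SE 0.32, adjusted p = 0.00111). Fkbp5, a glucocorticoid receptor co-chaperone gene, rose from 2.22 ± 2.06 to 9.01 ± 2.30 (log2 change 1.78, SE 0.33, adjusted p = 7.75e-05). Gadd45g fell from 13.6 ± 3.23 to 2.41 ± 1.57 (log2 change -2.16, SE 0.35, adjusted p = 1.15e-06) and the carbonic anhydrase gene Car3 from 6.91 ± 1.18 to 1.44 ± 0.126 (log2 change -1.69). The adipokine gene Adipoq fell from 2.74 ± 0.753 to 0.626 ± 0.197 (log2 change -1.19, SE 0.27, adjusted p = 0.00671). Usp2, Arg2 and Gga1 rose by 1.21, 1.27 and 1.24, and Btg2 rose from 27.1 ± 2.18 to 83.0 ± 55.9 FPKM. Samd7, Try5, 1810009J06Rikl, Sel1l, B3galt2, Chac1 and Trnah-gug9 fell, with log2 changes between -1.63 and -1.16. Try5 belongs to a family of near-identical trypsinogen genes. Ins2 averaged 141 ± 40.0 FPKM against 181 and 23.5 in the vehicle libraries and Prss1 19143 ± 382 against 16866 ± 5470, and neither passed (log2 changes 1.06 and 0.22). Gcg and Cpa1 did not pass either, at 0.84 and -0.12.

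Of 16 glucocorticoid response genes in pancreas, Mt1, Fkbp5 and Mt2A rose, also adjusted over the list alone, and 13 did not pass. The list was called upward (adjusted p = 5.86e-19, and adjusted p = 0.576 with an estimated correlation), but not without vehicle replicate 1 (adjusted p = 0.135). Of 13 clock genes Usp2 rose and 12 did not pass, among them Per2 at 3.50 ± 0.655 against 1.13 ± 0.0350 FPKM (adjusted p = 0.0636). Adjusted over the list alone 2 clock genes rose, and the list was called (adjusted p = 1.7e-11, and adjusted p = 0.576 with an estimated correlation) whichever library was left out. Of 24 ATF4 target genes Chac1 fell and 23 did not pass, and adjusted over the list alone 2 fell. That list was called downward (adjusted p = 0.00645, and adjusted p = 0.981 with an estimated correlation), but not without vehicle replicate 2 (adjusted p = 0.439) or BKC100 replicate 2 (adjusted p = 0.585). Of 27 digestive enzyme genes Try5 fell and 26 did not pass, and the list was not called (adjusted p = 0.507).

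Another 6 lists were called in pancreas with at most 1 member passing. Macrophage markers were called upward (adjusted p = 0.00382, and adjusted p = 0.599 with an estimated correlation), but not without BKC100 replicate 1 (adjusted p = 0.24). Under median-ratio scaling the other 5 ended. These were islet genes (adjusted p = 3.05e-08), immediate early genes (adjusted p = 0.000213) and p53 targets (adjusted p = 2.1e-06) upward, with 0.583 each with an estimated correlation. Reg and pancreatitis genes (adjusted p = 7.75e-17) and erythroid genes (adjusted p = 7.24e-11) were called downward, with 0.576 each with an estimated correlation. With the scaling, their adjusted p was 0.247, and 0.279 for erythroid genes. Without vehicle replicate 1 the medians of Reg genes and erythroid genes were 0.31 and 0.79, and immediate early genes (adjusted p = 0.711) and p53 targets (adjusted p = 0.764) were not called. Without vehicle replicate 2 the islet median was -0.45. Without BKC100 replicate 1 the p53 median was -0.25 and immediate early genes were not called (adjusted p = 0.649), and without BKC100 replicate 2 the erythroid median was 0.01. Reg3b was at 306 FPKM in vehicle replicate 1 and 4.58 in vehicle replicate 2, against 13.3 and 2.99 in BKC100. Adjusted over the list alone, 3 immediate early genes rose and 1 fell, 1 p53 target rose, and 0 members of the other 4 lists passed.

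**Figure D3:**
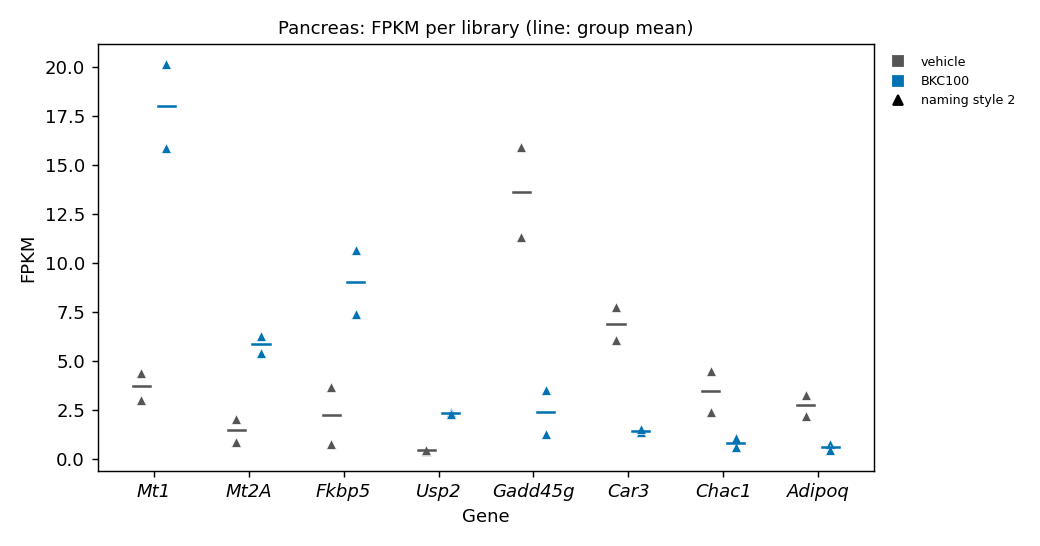
Pancreas FPKM on a linear axis for each library in vehicle and BKC100, with a line at each group mean. Mt1 lay at 15.8 and 20.2 in BKC100 against 3.03 and 4.40 in vehicle, and Adipoq at 0.766 and 0.487 against 3.28 and 2.21.

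Limma called 22 of 5610 pancreas genes, 9 up and 13 down, with 124 at an unadjusted p under 0.05 and an all-gene median of -0.07. With median-ratio scaling or quantile normalization 2 genes were called, both down, and of the 17 named genes that passed Car3 remained (adjusted p = 0.0355 with median-ratio scaling), while Mt1 (adjusted p = 0.359) and Fkbp5 (adjusted p = 0.736) did not. Their log2 changes with that scaling were 2.08 and 1.79, against 2.02 and 1.78 without it. Protein-coding genes at equal sums gave 17 calls, 8 up and 9 down, and kept 7 of the 17 named genes. Without BKC100 replicate 1 or BKC100 replicate 2, 0 genes passed, with 28 and 52 at an unadjusted p under 0.05. Without vehicle replicate 2, 115 passed (15 up and 100 down), 12 of the 17 among them, and without vehicle replicate 1, 32 passed (22 up and 10 down) and 8 of the 17 remained. Fkbp5 did not pass without vehicle replicate 1 (adjusted p = 0.106), and Gadd45g did not pass without vehicle replicate 1 (adjusted p = 0.516) or replicate 2 (adjusted p = 0.215). With no filter on low values, 0 genes passed (620 at an unadjusted p under 0.05). Rn7sl1 took 23.6% and 19.8% of FPKM in BKC100 against 14.5% and 15.9% in vehicle.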

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

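All tests in this part were chosen after the results they bear on were seen.

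The metallothionein genes moved in opposite directions in adrenal gland and pancreas at 100 µg BKC. The limma interaction over 8 libraries gave an adrenal minus pancreas difference of -4.43 for Mt1 (SE 0.40, adjusted p = 9.2e-26) and -5.03 for Mt2A (SE 0.38, adjusted p = 1.82e-35), on the log2 scale. Unlike the fits of each organ apart, it took a common spread per gene over both organs, shrunk toward other genes. Libraries with the same animal label in both organs were treated as independent. The size of these p values therefore does not measure how these genes vary between animals. Mt1 changed by -2.41 in adrenal gland and 2.02 in pancreas, and Mt2A by -3.51 and 1.52. In pancreas alone, neither rise passed with median-ratio scaling, quantile normalization or no filter on low values. The alternatives run for the difference were a pseudocount of 0.1, the replicate block, median-ratio scaling and each of the 8 libraries left out. No filter, quantile normalization and protein-coding genes at equal sums were not run for it. Both differences passed in 11 of 11 alternatives, with adjusted p from 4.85e-40 to 0.0149 for Mt1 and from 4.56e-48 to 0.00979 for Mt2A. In total 212 of 5280 genes passed, 83 with a more positive and 129 with a more negative change in adrenal gland, against 27 and 19 with median-ratio scaling and 7 and 6 without pancreas vehicle replicate 2. The adrenal BKC100 libraries had another naming style than their vehicle, and the pancreas libraries had 1 style.

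The heart BKC100 replicate 2 column held adrenal genes. It had 6453 FPKM of Star, against 0.122 and 0.346 in the vehicle hearts, and 2043 FPKM of Cyp11b1, against 0 and 0, while Myh6, Myl2 and Nppa were at 0. The column equalled the adrenal BKC100 replicate 2 column in every gene, and between any other 2 libraries at most 0.0110% of genes above 0 had equal values. It correlated with the other adrenal libraries at 0.979 to 0.984 and with the hearts at 0.847 to 0.860, across genes. No biological explanation was tested.

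The remaining BKC100 heart library was high in atrial and low in ventricular genes. The 8 ventricular genes had a median log2 difference of -3.0 from vehicle and 8 of 8 lay below all 4 other hearts, while 9 of 11 atrial markers lay above them with a median of 3.33. Atrial tissue in the piece in place of left ventricle may explain the pattern, since Myl7, Myl4, Sln and Bmp10 reached 1704 to 7906 FPKM. Of 12 stress genes outside the chamber lists, 7 (58.3%) lay above all 4 other hearts and 4 below, against 20.0% expected by chance for each, so atrial tissue and a stress response of ventricular tissue cannot be told apart with genes that went both ways in 1 library. An effect of BKC stays open, as untested with 1 library.

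The adrenal BKC100 libraries differed from vehicle in dose and in naming style. The hearts hold both styles within vehicle and within BKC50, with 1 library of each style per group. Their style difference is free of dose, but not of differences between animals, pieces or replicate numbers. Across 149 small nucleolar RNA genes, the style difference in heart and the BKC100 difference in adrenal gland correlated at 0.710, so a shift between styles may account for these. All 3 called clock genes (Per2, Npas2 and Bmal1) went the same way in both heart groups. Per2 and Npas2 did so by 0.79 and -0.64 against 1.80 and -1.47 in adrenal gland (SE 0.33 and 0.30). The style difference of Bmal1 in heart lay closer to its adrenal fall. Within the first style, adrenal Per2 lay at 3.38 and 3.53 FPKM in BKC50 against 1.42 and 1.70 in vehicle (adjusted p = 0.392). Npas2 lay at 3.99 and 4.88 against 6.18 and 7.13 (adjusted p = 0.558). Dose and style cannot be told apart for these 3 genes. The 9 cholesterol genes that rose had a median style difference of -0.46 in heart (from -0.63 to 0.11), against adrenal rises of at least 0.73, which argues against a shift common to both organs for that group. Of the 877 coding genes that fell and were also tested in heart, 82.9% were lower in the second style of the hearts, against 67.0% of 10256 coding genes, so dose and style cannot be told apart for the falls, and an adrenal response to 100 µg BKC and a style difference in adrenal gland only stay open for each group.

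Adipoq and Car3, both abundant in fat cells, fell in the BKC100 pancreas. Of 15 other adipocyte markers, 11 (73.3%) were lower in both BKC100 libraries than in both vehicle libraries and 0 were higher, against 16.7% expected by chance. Fabp4 was at 10.5 and 9.05 against 24.2 and 16.8 FPKM and Cfd at 2.34 and 1.72 against 4.99 and 4.33, but Lpl at 13.1 and 11.7 against 13.5 and 9.27. Less fat tissue in the BKC100 pieces and lower expression in fat cells cannot be told apart, because Lpl is also made by other cells and most of these markers lay under 1 FPKM. Median-ratio scaling took away 4.23% of the mean log2 fall of Adipoq and Car3, which argues against the differences it corrects as the whole cause. Its size factors were 1.25 and 0.851 in vehicle and 1.01 and 0.930 in BKC100. How far the other scalings change the fall is not given here. With median-ratio scaling Adipoq no longer passed in limma (log2 change -1.14 against -1.19 before, adjusted p = 0.0655), while Car3 did (adjusted p = 0.0355). Neither gene passed under every alternative.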

How the results depend on the processing

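The scalings, the limma fit without robust shrinkage, all 6 heart columns and the organ interaction were chosen after the data were seen, and the other alternatives were planned. Where no cause is given below, the cause was not tested. The count tests (edgeR, DESeq2 and voom), the count-based scalings and filters and the planned test across 3 organs were not run, because the values are not counts. Depth per library is unknown, so a gene at 0 or near 1 FPKM cannot be called absent.

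With no filter on low values 0 genes were called at BKC50 and BKC100 against vehicle and between the doses in adrenal gland and 0 in pancreas (limma, 2005, 4551, 3027 and 620 at an unadjusted p under 0.05), and 565 and 556 for the BKC100 heart against vehicle and BKC50. With a pseudocount of 0.1 the counts were 0 for adrenal BKC50 (1356 at an unadjusted p under 0.05), 60 for the BKC100 heart against BKC50 and 127 for the adrenal against pancreas difference. At least a 2-fold change left 768 for adrenal BKC100. Only the 2 groups compared gave 184 for adrenal BKC50, and 265 and 577 for the BKC100 heart against vehicle and BKC50. With the replicate block the counts were 0, 526 and 72 in adrenal gland (BKC50, BKC100 and between the doses, 1334 at an unadjusted p under 0.05 for BKC50), 5327 and 5490 for the BKC100 heart, 44 in pancreas and 453 for the organ difference. Replicate numbers did not pair the adrenal libraries, whose replicate differences correlated between groups at -0.145 to 0.143 across genes. In heart that correlation was 0.743, where the number coincides with naming style in vehicle and BKC50, and in pancreas it was 0.423. The lone BKC100 heart is replicate 1 but of the second style. The block set it beside replicate 1 hearts of the first style, so the BKC100 heart counts with the block also hold the style difference. With naming style as a covariate the BKC100 heart gave 3545 and 3668.

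Median-ratio scaling gave 0, 330 and 38 in adrenal gland (1523 at an unadjusted p under 0.05 for BKC50), 255 and 244 for the BKC100 heart, 2 in pancreas and 46 for the organ difference. Quantile normalization gave 0, 397 and 33 in adrenal gland (1627 for BKC50), 302 and 292 in heart and 2 in pancreas. Protein-coding genes at equal sums, with fewer genes tested, gave 2, 551 and 165 in adrenal gland, 432 and 480 in heart and 17 in pancreas. Limma without robust shrinkage gave 0 for adrenal BKC50 (1407 at an unadjusted p under 0.05) and 161 between the doses. All 6 heart columns as deposited gave 0 for both BKC100 heart comparisons (1411 and 1441), where an adrenal library then entered the group. At an unadjusted p under 0.01 the dose overlap was 206 genes in adrenal gland and 2 in heart.

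Heart BKC50 gave 0 calls in every other alternative (limma, 5 to 588 at an unadjusted p under 0.05). With each library left out in turn the counts ranged from 1 to 183 for adrenal BKC50, from 261 to 2304 for adrenal BKC100, from 81 to 870 between the adrenal doses, from 0 to 2 for heart BKC50 (limma, 44 to 104 at an unadjusted p under 0.05 where 0 were called), from 266 to 347 and from 105 to 579 for the BKC100 heart against vehicle and BKC50, from 0 to 115 in pancreas (28 and 52 at an unadjusted p under 0.05 without BKC100 replicates 1 and 2) and from 13 to 370 for the organ difference. Where this left 1 library in a group, that library was assumed to vary like the other groups. List medians that changed sign, or whose test changed direction, ranged as follows. At adrenal BKC50, interferon genes ranged from -1.05 to 0.22 and cell cycle genes from -0.55 to -0.022. At heart BKC50, collagen genes ranged from -0.33 to 0.11 and interferon genes from -0.082 to 0.46. In pancreas, islet genes ranged from -0.45 to 1.29, Reg genes from -0.85 to 0.31, erythroid genes from -2.35 to 0.79 and p53 targets from -0.25 to 0.75.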

Other observations

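All tests in this part were chosen after the results were seen.

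Heart libraries of different naming styles differed in many genes, of which those named here were picked after their values were seen, and no gene list was tested for style. Each style was present once in vehicle and once in BKC50, so the difference was tested with treatment in the model (limma, 5 libraries, 1 residual degree of freedom). Among fatty acid oxidation genes and PPAR targets, the second style had more of Angptl4 (log2 difference 3.58, adjusted p = 0.00486), Pdk4 (2.65, adjusted p = 0.0045) and Ucp3 (1.44, adjusted p = 0.0128). It had less of Plin5 (-0.73, adjusted p = 0.0108), of the same list, and less of Klf15 (-0.89, adjusted p = 0.0102). The clock genes Per2 (0.79, adjusted p = 0.0115) and Per3 (0.95, adjusted p = 0.0232) were higher in the second style. Bmal1 (-0.79, adjusted p = 0.0119), Npas2 (-0.64, adjusted p = 0.0200) and Nr1d1 (-1.33, adjusted p = 0.0260) were lower. In total 4205 of 12099 genes differed, 1045 higher and 3160 lower in the second style, against 0 between BKC50 and vehicle (limma, 588 at an unadjusted p under 0.05 in the same model).

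Across genes, the style difference in heart correlated with the adrenal BKC100 difference at 0.296 over 10774 genes, at 0.192 over coding genes, 0.280 over long non-coding RNA genes, 0.295 over small nuclear RNA genes and 0.710 over small nucleolar RNA genes. Genes are not independent replicates. What the naming styles stand for was not given in the sources used here.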
